A study of Homo sapiens with 32 samples.

How the data were processed

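The series measured messenger RNA by sequencing in N/TERT-2G cells, an immortalized human keratinocyte line. The cells carried a tetracycline (Tet) switched short hairpin RNA against TRAF3IP2, the gene that encodes Act1, an adaptor protein of the IL-17 receptor. Per the labels, each of 8 groups (with or without Tet, combined with no cytokine, IL-17A, TNF, or IL-17A plus TNF) held 4 libraries, 1 from each of 4 repeats of the whole experiment with batch ids 2, 3, 4 and 5, which gives 32 libraries. Per the labels' protocols, cells were seeded in serum-free medium with 0.4 mM calcium chloride and grown for 7 days, and 1 µg/ml Tet was added on the day after seeding. The doses and times of cytokine exposure are not given in the sources used here. Polyadenylated RNA was made into libraries with Illumina's mRNA-Seq kit, a kind that does not mark strand, and read on a Genome Analyzer IIx, per the labels' protocols.

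The authors deposited 1 table per library with a raw count and an RPKM value for each of 21510 gene symbols, per the file headers. Bowtie and TopHat are named in the submitters' processing notes without versions or roles, and the counting program, genome build and annotation are not given in the sources used here. The deposited counts were whole numbers with a different total in each library. The deposited RPKM values (counts scaled by gene length and library total) were, by calculation, the counts divided by 1 length per gene and by the library total (largest deviation 0.0384%), so they carry no further correction and were not used in any test. No symbol was blank, no library pair was identical, and the most similar pair within a group differed well beyond sampling noise (chi-square per degree of freedom 45.2), so all 32 libraries were kept as separate replicates. The labels do not say how the 4 repeats were grown apart, so p-values measure the spread between these repeats of 1 cell line.

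Library totals ran from 28.6 to 59.0 M counts (median 33.7; 1 M is 10⁶ counts). Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, default low-count filter on the 8 groups) in 1 model of all 32 libraries with 8 group means and the batch as a block; 14204 genes passed the filter. The common dispersion was 0.0209, a coefficient of variation of 14.4% that remained after group and batch differences were removed. Each of 12 comparisons was a two-sided contrast in this model, with Benjamini-Hochberg adjustment over the 14204 genes and calls at an adjusted p under 0.05. An interaction is the difference between 2 responses. Levels are TMM-scaled counts per 10⁶ counts of the library (CPM), mean ± SD over the 4 batches of a group, and values per batch are log2 differences within that batch with a prior count of 2. The target gene was also tested with an exact sign-flip permutation over the 4 batches. These designs, the gene lists and the rule for named genes were set before the data were examined.

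On simulated counts for the 14204 genes with 200 genes changed, edgeR recovered 77.6%, 95.5% and 97% of genes changed 1.5, 2 and 4-fold in the comparison of Tet without cytokine, with 9 false calls. For the IL-17A response the shares were 71.6%, 94% and 100% with 11 false calls, and for the Tet by IL-17A interaction 34.3%, 89.6% and 100% with 7 false calls. A simulated list shifted 1.5-fold ranked 1 among the lists in the simulated IL-17A response. The simulated counts were drawn independently and the changed genes had a mean of at least 2 CPM. They lacked the deviation that real libraries of 1 Tet arm of a batch share. The shares and false calls therefore do not measure how the Tet comparisons perform on the real libraries.

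The batch ids pair the libraries, as the series' design text describes. This was checked on deviations from the group means: all 112 pairs of libraries from 1 batch correlated at 0.207 or more (median 0.588), the median over other pairs was −0.228, and each of the 32 libraries correlated best with a library of its own batch. Libraries of 1 batch with the same Tet setting were closer (median 0.702) than those with different Tet settings (0.535). Libraries of 1 Tet arm of a batch are therefore not independent in the Tet comparisons. For that reason, and after the data were seen, 2 further fits were added: counts summed over the 4 conditions of each arm and batch for the mean Tet effect, and a block for each batch within each Tet arm for the cytokine responses and interactions.

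Fixed lists covered 22 gene groups, of which 19 had at least 3 tested members: antimicrobial proteins and alarmins, chemokines and regulators described as IL-17 targets, TNF and NF-kB targets, interferon-stimulated genes, early differentiation markers, late cornified-envelope markers, small proline-rich and LCE3 proteins, desquamation proteases, barrier lipid genes, differentiation transcription factors, basal markers, hyperproliferation keratins, cell-cycle genes, cholesterol genes, ATF4 and integrated stress response targets, immediate early and heat shock genes, receptor signalling components, and markers of fibroblasts and leukocytes. Of the markers of melanocytes 2 were tested and of endothelial cells 1, too few for a list test, and none of the 13 mitochondrially encoded genes was tested. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with the rotation test fry, with adjustment over the 19 lists of a comparison. Over 228 pairs of list and comparison, camera called 86, of which 23 held with an estimated correlation.

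The text names TRAF3IP2 in each comparison. Called genes with the same sign in all 4 batches and a mean of at least 2 CPM were ranked by size of change. The rankings held up to 10 genes in each direction for the mean Tet effect and the cytokine responses without Tet, and 5 elsewhere. The text names some genes of these rankings and leaves others out. For each list described the text names up to 4 members with the smallest p, and values of members that did not pass. Genes named for another reason are said to be chosen after their values were seen. Counts of a list are given over all genes tested and adjusted over the list alone.

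Alternatives were DESeq2 1.42.0 with the same design, no batch block, median-of-ratios scaling, no low-count filter, a stricter filter (2 CPM in 4 libraries), a requirement of a 2-fold change, fits on the compared groups alone, each pair of batches that shares a number in the library titles, and each library or batch left out in turn. The shRNA target was placed on the GRCh38 genome with GENCODE annotation, and 3′ untranslated regions of the same annotation were searched for short matches to its guide strand; 92.8% of the tested symbols matched that annotation. Near-identical genes (DEFB4A, the SPRR2, LCE3, CEACAM, SAA and S100A7 families) and overlapping genes can exchange reads under an unstated counting rule, so their values are uncertain.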

Results

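Messenger RNA was sequenced from N/TERT-2G keratinocytes, an immortalized human skin line, in which Tet turned on a short hairpin RNA against TRAF3IP2. The design asked what the Act1 protein encoded by that gene does for keratinocyte differentiation and for the defence genes that IL-17A turns on, alone or with TNF. There were 8 groups of 4 libraries, 1 per batch, each with or without Tet and with no cytokine, IL-17A, TNF, or both cytokines. The 32 libraries held 28.6 to 59.0 M counts each (median 33.7; 1 M is 10⁶ counts), and a count was found for 15680 to 16717 gene symbols per library. The mean total was 34.7 ± 7.17 M (SD, n = 16) without Tet and 34.4 ± 2.90 M (SD, n = 16) with Tet.

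TRAF3IP2, the target of the hairpin, fell 7.60-fold with Tet in the absence of cytokine. Its level was 97.2 ± 9.82 CPM without Tet and 12.95 ± 3.27 CPM with Tet (SD, n = 4 batches each; edgeR log2 −2.93, SE 0.112, adjusted p = 7.75e-16). The share that remained was 13.3% without cytokine, 12.4% with IL-17A, 13.9% with TNF and 11.5% with both, and the highest library with Tet (17.8 CPM) lay below the lowest without (78.2 CPM). Averaged over the 4 conditions, the log2 difference was −2.98 (SD 0.188 over 4 batches), with −2.96, −2.77, −3.23 and −2.98 in batches 2 to 5. An exact two-sided sign-flip permutation test gave p = 0.13, the smallest that 4 batches allow. The cytokines did not change TRAF3IP2 past the threshold without Tet: the log2 values were 0.13 for IL-17A (adjusted p = 1), −0.14 for TNF (0.333) and 0.09 for both (0.531). With Tet the corresponding values were 0.02 (0.999), −0.08 (0.649) and −0.10 (0.545). The hairpin's target sequence, GCCAGATGCTTGTGTATCCTC, lies on the minus strand of chromosome 6 at 111558989 to 111559009 (GRCh38), in the last exon and the 3′ untranslated region of TRAF3IP2, and is present in 7 of its 12 annotated transcripts.

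**Figure D1:**
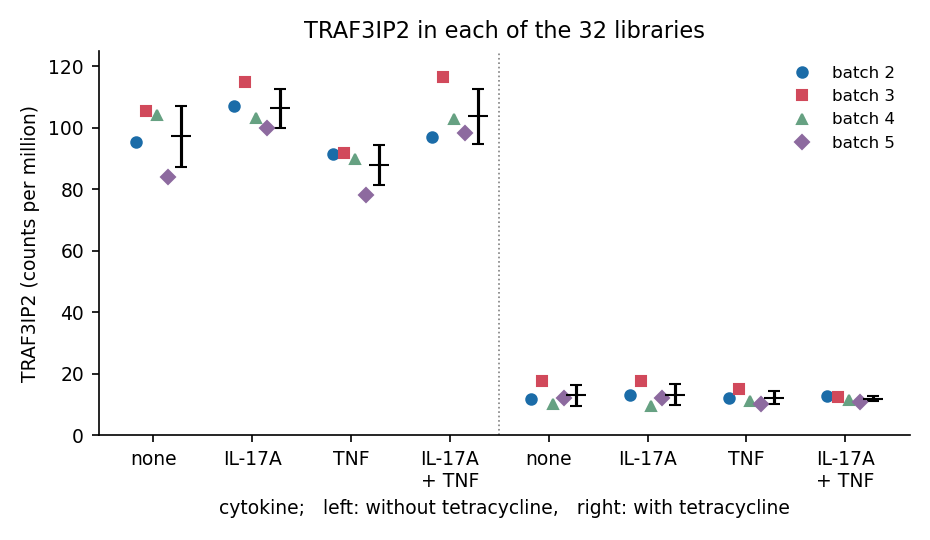
Level of TRAF3IP2 in CPM in each of the 32 libraries, by cytokine and by Tet. The libraries with Tet reach at most 17.8, and those without Tet are at 78.2 or above.

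Without cytokine, the question was what the knockdown does to resting keratinocytes, and the gene of a suprabasal keratin, KRT10, was lower with Tet. KRT10, a structural keratin of early differentiation, fell 5.95-fold with Tet (log2 −2.57, SE 0.424, adjusted p = 0.000392, edgeR), from 707 ± 463 to 113 ± 88.4 CPM (SD, n = 4), and the differences in batches 2 to 5 were −3.74, −0.673, −3.98 and −2.43. CXCL14, a chemokine of unstimulated epithelium, fell 11.7-fold (SE 0.559 on the log2 scale, adjusted p = 0.000255), and the collagen cross-linking enzyme LOX fell 5.51-fold (adjusted p = 0.00101). The protease MMP9 fell 2.70-fold (adjusted p = 9.83e-06) and the cytokine IL32 fell 2.43-fold (9.39e-05). LCN2, an iron-binding antimicrobial protein, rose 3.62-fold (log2 1.86, SE 0.279, adjusted p = 0.000154), from 19.96 ± 1.93 to 78.6 ± 37.2 CPM, and the adhesion molecule CEACAM6, with reads uncertain within its gene family, rose 5.89-fold (6.58e-05). The mucosal keratin KRT4 rose 2.21-fold (adjusted p = 0.00301), and KRT1, the partner of KRT10, fell 4.13-fold (0.00961). KRT1 did not pass without the Tet library of batch 2 (log2 −1.69, adjusted p = 0.0503) or without batch 2 or 5 (0.0871 and 0.0759), and KRT4 did not without batch 5 (0.0504). The SEs and p-values of this comparison can be too small, because the model takes libraries of 1 Tet arm of a batch as independent. The SD of the difference over the 4 batches was 1.52 for KRT10 and 0.917 for LCN2. In total 729 genes rose and 806 fell, and in a fit of these 8 libraries alone 98 rose and 169 fell. Of 20 early differentiation markers 1 rose and 5 fell (3 and 6 adjusted over the list alone), and camera gave adjusted p = 0.0141 downward (adjusted p = 0.886 with an estimated correlation). Camera called 5 of the 19 lists in this comparison, 2 of them upward, and 0 held with an estimated correlation. Of 18 antimicrobial genes 4 rose and 2 fell over all genes tested and adjusted over the list alone (camera adjusted p = 0.407), with RNASE7 2.52-fold higher (0.00475) and S100A7, an alarmin with a near-identical neighbour, 2.32-fold lower (0.00371). Without batch 2 or 4 the value for RNASE7 was 0.0726 or 0.0622, and without batch 5 that for S100A7 was 0.0504. The total of 1535 changed to 201, 2346, 695 and 604 when batch 2, 3, 4 or 5 was left out. It was 870 and 778 without the control library of batch 2 or 4, and 761, 960 and 859 without the Tet library of batch 2, 4 or 5.

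Averaged over the 4 conditions, Tet lowered KRT1 5.56-fold (log2 −2.48, SE 0.277, adjusted p = 9.29e-08, edgeR), with differences of −3.34, −1.94, −1.26 and −2.91 in batches 2 to 5, and raised the small proline-rich envelope protein SPRR3 2.56-fold (log2 1.36, SE 0.166, adjusted p = 3.42e-07), with differences of 1.29 to 1.51. The SEs and p-values of the mean Tet effect take the 4 conditions of an arm as independent, which they are not, so they can be too small. For KRT1 the SD over the 4 batches was 0.941. In the summed counts described below, 3 of the named values lost their call. CXCL14 fell 11.5-fold (log2 −3.53, SE 0.286, adjusted p = 5.59e-10), the matrix protease MMP13 fell 6.77-fold, the receptor kinase ROS1 6.57-fold, the collagen COL5A3 5.55-fold, the protease inhibitor SERPINA3 5.32-fold, LOX 5.18-fold and the chemokine CCL5 4.52-fold. Among differentiation genes, the desmosomal cadherin DSC1 fell 3.43-fold, the surface protein LY6D 2.52-fold, KRT10 2.33-fold (adjusted p = 2.52e-05) and KRTDAP 2.18-fold, while KRT4 rose 2.01-fold. The KRT10 differences were −1.77, −0.352, −1.68 and −1.25 in batches 2 to 5, and its call ended in batches 2 and 3 alone (adjusted p = 0.0503). IL1RL1, the receptor for IL-33, rose 5.69-fold (log2 2.51, SE 0.271, adjusted p = 5.38e-08). CEACAM6 rose 4.31-fold, MMP1 3.11-fold, the cornified-envelope gene CRCT1 3.00-fold and LCE3E 2.53-fold, with reads of the CEACAM and LCE3 families uncertain. In total 3680 genes rose and 3616 fell, of which 4758 had the same sign in all 4 batches, and 151 and 293 changed by 2-fold or more. When the counts of each Tet arm of a batch were summed, which treats each arm as 1 culture and was chosen after the data were seen, 457 genes rose and 734 fell. All 1191 had the same sign in both fits.

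**Figure D2:**
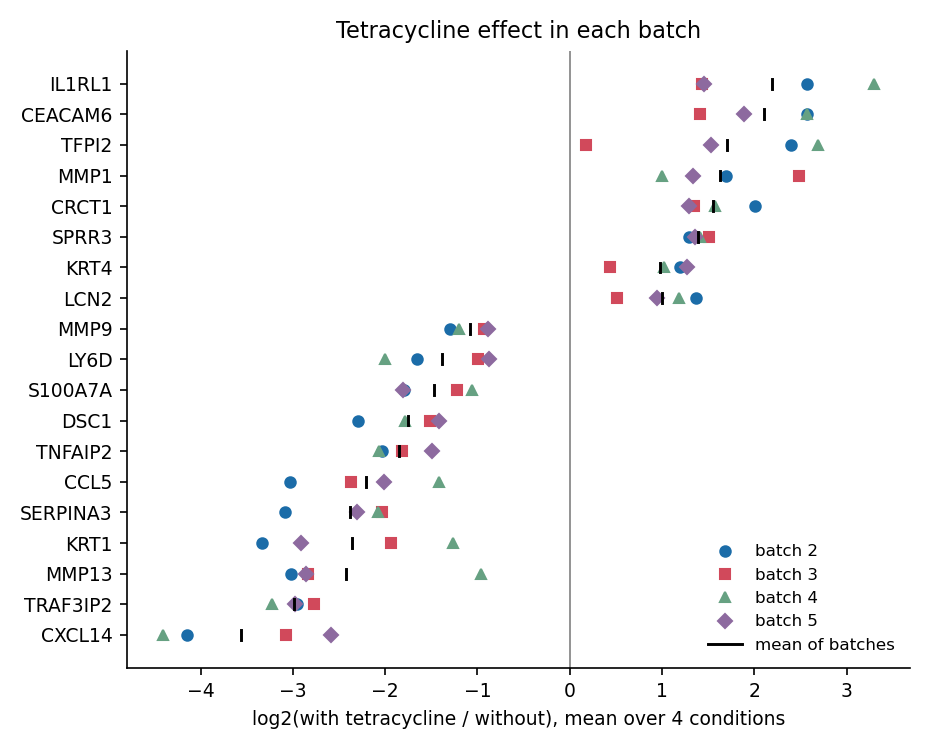
Log2 difference between libraries with and without Tet, averaged over the 4 cytokine conditions, in each batch for selected genes; the black tick marks the mean of the 4 batches. TRAF3IP2 lies between −3.23 and −2.77, and CXCL14 between −4.41 and −2.59.

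By gene group, the mean Tet effect ran downward for TNF and NF-kB targets and upward for small proline-rich and LCE3 proteins. Of 27 TNF and NF-kB targets 1 rose and 15 fell (1 and 17 adjusted over the list alone; 0 and 12 in the summed counts), with TNFAIP2, a TNF-induced gene, 3.49-fold lower (adjusted p = 1.23e-07), the complement factor CFB 2.84-fold lower and MMP9 2.11-fold lower. Camera gave adjusted p = 1.21e-05 for this list (adjusted p = 0.393 with an estimated correlation). Of 15 small proline-rich and LCE3 genes 12 rose and 1 fell over all genes tested and adjusted over the list alone (10 and 0 summed), and camera gave 1.21e-05 (adjusted p = 0.461 with an estimated correlation). Of 18 antimicrobial genes 5 rose and 7 fell, also adjusted over the list alone (3 and 3 summed; camera adjusted p = 0.713, and in the summed counts 0.00942, adjusted p = 0.561 with an estimated correlation): S100A7 fell 2.48-fold, while RNASE7 rose 2.16-fold and LCN2 2.02-fold. Of 20 early differentiation markers 4 rose and 12 fell (4 and 13 adjusted over the list alone; 1 and 6 summed; camera 0.0216, adjusted p = 0.779 with an estimated correlation). Of 28 interferon-stimulated genes 2 rose and 12 fell (2 and 14 adjusted over the list alone; 0 and 2 summed), with CXCL10 2.99-fold lower (camera 0.0282, adjusted p = 0.796 with an estimated correlation). Of 20 cholesterol genes 14 rose and 1 fell over all genes tested and adjusted over the list alone, but only 1 rose and 0 fell in the summed counts, with the sterol sensor INSIG1 1.76-fold higher (camera 0.00812, adjusted p = 0.779 with an estimated correlation). The list's median differed between batches 2 to 5: 0.175, −0.265, 0.942 and 0.447. Of 14 desquamation protease genes 9 rose (10 adjusted over the list alone; 1 summed), led by KLK10 at 1.56-fold (camera 0.0123, adjusted p = 0.779 with an estimated correlation). Of 22 receptor signalling components, TRAF3IP2 among them, 6 rose and 12 fell, also adjusted over the list alone (0 and 2 summed, TRAF3IP2 again among them; camera 0.00113, adjusted p = 0.13 with an estimated correlation), and the kinase IKBKE fell 1.76-fold.

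The other lists had no camera call for the mean Tet effect over the 32 libraries. Of 17 chemokines and regulators described as IL-17 targets 7 rose and 5 fell (1 and 2 summed; camera adjusted p = 0.713), of 19 late cornified-envelope markers 9 rose and 2 fell (1 and 2 summed; 0.23), of 22 barrier lipid genes 5 rose and 7 fell (2 and 2 summed, 0.95), and of 16 differentiation transcription factors 3 rose and 5 fell (2 and 5 summed, 0.713), with NOTCH1 1.76-fold higher and MAF 3.08-fold lower. Basal markers gave 5 rising and 8 falling of 20 (0 and 1 summed, 0.389), hyperproliferation keratins 0 of 5 in both fits (0.713), cell-cycle genes 3 rising and 3 falling of 26 (0 and 0 summed, 0.971), and immediate early and heat shock genes 5 and 3 of 16 (1 and 1 summed, 0.95). Of 6 fibroblast markers 4 fell (2 summed; camera 0.0808, and in the summed counts 0.00942, adjusted p = 0.461 with an estimated correlation), among them COL1A1, 2.80-fold lower (adjusted p = 1.25e-07), and of 3 leukocyte markers CD68 rose 1.79-fold (1 also summed, camera 0.353). Of 20 ATF4 and integrated stress response targets, GDF15 rose and DDIT4 fell (1 and 0 summed, camera 0.78). The median of this list was 0.0711, 0.708, −1.60 and 0.233 in batches 2 to 5. In batch 4 the amino-acid synthesis enzyme ASNS fell from 482 ± 63.7 to 57 ± 26.5 CPM (SD over the 4 conditions of that batch) and the cystine carrier SLC7A11 from 114 ± 16.9 to 5.86 ± 2.99 CPM. For the Tet effect, mean of 4 conditions, 5932 genes were called without batch 4, against 7296 with it.

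**Figure D3:**
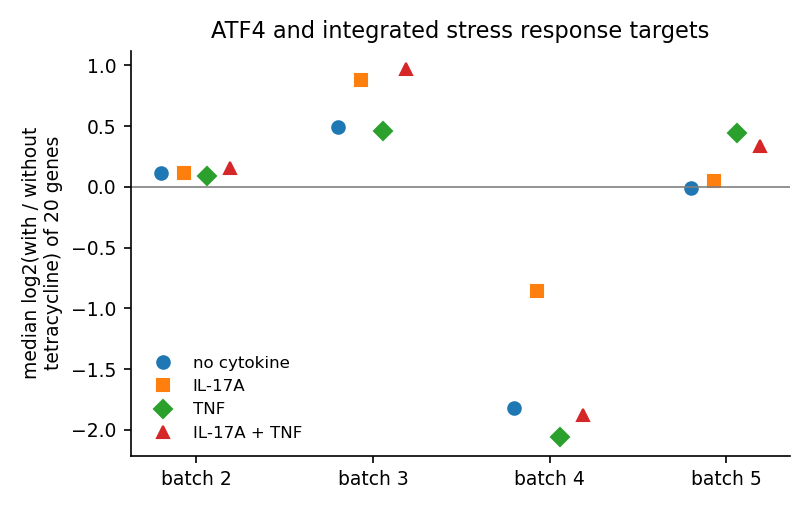
Median log2 difference between libraries with and without Tet for 20 ATF4 and integrated stress response targets, in each batch and cytokine condition. In batch 4 the 4 conditions lie between −2.06 and −0.859.

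IL-17A alone, without Tet, raised a small group of defence genes. LCN2 rose 4.09-fold (log2 2.03, SE 0.28, adjusted p = 0.000408, edgeR), from 19.96 ± 1.93 to 94.4 ± 59.96 CPM (SD, n = 4), and by 1.33, 1.83, 3.26 and 1.83 in batches 2 to 5. NFKBIZ, a transcriptional partner of NF-kB, rose 2.96-fold (log2 1.56, SE 0.201, adjusted p = 0.000151) and the RNA-degrading feedback gene ZC3H12A 2.48-fold (log2 1.31, SE 0.141, adjusted p = 1.44e-05). SAA4, an acute-phase gene with reads uncertain within its family, rose 5.53-fold (adjusted p = 0.000136), and PDZK1IP1, a membrane adaptor, rose 2.73-fold (0.00109). The defensin DEFB4A, which has a near-identical copy, had 144 counts with IL-17A against 6 without, a ratio of 23.1 (interval for counting error only 10.4 to 64, adjusted p = 0.00233). The IL-17A libraries held 7 to 70 of these counts, and the DEFB4A differences in batches 2 to 5 were 1.08, 2.9, 4.44 and 3.76. These 6 genes kept their calls with any single library left out, but without batch 5 LCN2 and PDZK1IP1 had adjusted p = 0.0609 and DEFB4A 0.192, and without batch 4 DEFB4A had 0.13. The transcript C15orf48, which overlaps MIR147B, was among the other called genes (log2 1.55, adjusted p = 0.0248), but that call ended without the control library of batch 2, 4 or 5 (adjusted p = 0.0656, 0.302 and 0.161) or the IL-17A library of batch 3 or 4 (0.137 and 0.16). KRT10 gave −1.87 (SE 0.406, adjusted p = 0.0577) and the chemokine CCL20 rose from 16.9 ± 6.07 to 29.6 ± 12.6 CPM without passing the threshold.

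In total 20 genes rose and 2 fell with IL-17A, and in a fit of the 8 compared libraries alone 40 rose and 33 fell. Of 18 antimicrobial genes 7 rose (13 adjusted over the list alone; camera 5.02e-66, adjusted p = 4.29e-07 with an estimated correlation), of 17 IL-17 target chemokines and regulators 5 rose (6 adjusted over the list alone; 3.6e-31 and 8.84e-05), and of 15 small proline-rich and LCE3 genes 5 rose (7 adjusted over the list alone; 4.74e-20 and 0.0137). The early differentiation list ran downward by camera (1.5e-08), adjusted p = 0.136 with an estimated correlation. All 6 fibroblast markers were lower, none past the threshold, with a median of −0.315 and camera adjusted p = 0.000402 (adjusted p = 0.00489 with an estimated correlation). The count of 22 moved to 10, 10, 7 and 3 without batch 2, 3, 4 or 5. It was 7, 14, 6 and 14 without the control library of batch 2, 3, 4 or 5, and 8, 8 and 13 without the IL-17A library of batch 3, 4 or 5.

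TNF alone, without Tet, changed far more genes and raised most of the TNF and NF-kB targets listed. The adhesion molecule ICAM1 rose 12.9-fold (log2 3.69, SE 0.372, adjusted p = 1.53e-07, edgeR), by 3.34, 3.79, 3.3 and 3.94 in batches 2 to 5, and IL32 rose 6.10-fold (log2 2.61, SE 0.187, adjusted p = 1.14e-09). The growth factor CSF2 rose 44.0-fold, from 0.264 ± 0.211 to 10.03 ± 3.19 CPM (SE 0.704 on the log2 scale, adjusted p = 4.19e-06), SCNN1D, a sodium channel subunit, 15.4-fold, C15orf48 13.3-fold, and TNFAIP2 12.5-fold, and the adaptor TRAF1 had a log2 difference of 3.70. The alarmin subunit S100A9 rose 3.34-fold (adjusted p = 5.45e-08) and LCN2 4.81-fold (2.58e-06), and DEFB4A had 107 counts against 6, a ratio of 19.1 (interval for counting error only 8.51 to 53.3). KRT10 fell 6.25-fold (log2 −2.64, SE 0.417, adjusted p = 5.26e-05), by −2.26 to −3.12 in the 4 batches, KRT4 fell 2.49-fold and the non-coding RNA H19 6.52-fold. The envelope genes CNFN and CRCT1 rose 6.05-fold and 10.2-fold. The basement membrane chains LAMB3 and LAMA3 had log2 differences of 0.81 and 0.97. Among cell-cycle genes the motor KIF11 fell 1.82-fold and the cyclin CCNA2 2.07-fold.

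In total 1667 genes rose and 1591 fell with TNF. Of 27 TNF and NF-kB targets 25 rose (26 adjusted over the list alone; camera 6.82e-41, adjusted p = 0.000374 with an estimated correlation), of 18 antimicrobial genes 15 rose, also adjusted over the list alone (0.00306 estimated), of 17 IL-17 target chemokines and regulators 13 rose (14 adjusted over the list alone; 0.00804 estimated), and of 15 small proline-rich and LCE3 genes 12 rose (13 adjusted over the list alone; 0.0449 estimated). Of 26 cell-cycle genes 19 fell (23 adjusted over the list alone; camera 1.56e-09, adjusted p = 0.218 with an estimated correlation), with batch medians of −0.784, −1.23, −0.337 and −0.439. Of 28 interferon-stimulated genes 7 rose (8 adjusted over the list alone; camera 0.0041, adjusted p = 0.629 with an estimated correlation). The total of 3258 moved to 1939, 1818 and 2151 without batch 2, 3 or 5.

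IL-17A and TNF together, without Tet, gave higher mean levels of DEFB4A and LCN2 than either cytokine alone, a difference not tested in itself. DEFB4A reached 38.6 ± 10.9 CPM (SD, n = 4), with 5794 counts against 6, a ratio of 885 (interval for counting error only 407 to 2410). LCN2 rose 22.5-fold to 482 ± 171 CPM (log2 4.49, SE 0.308, adjusted p = 1.07e-10, edgeR), by 4.03, 4.53, 5.23 and 4.34 in batches 2 to 5. The cytokine subunit IL23A rose 31.1-fold (log2 4.96, SE 0.445, adjusted p = 7.63e-09), CSF2 96.3-fold, the neutrophil growth factor CSF3 57.4-fold, C15orf48 38.8-fold, and the neutrophil chemokine IL8 26.0-fold, and SAA4 had a log2 difference of 4.46. S100A9 rose 5.07-fold, NFKBIZ 5.84-fold, ZC3H12A 3.49-fold and SPRR2E, read with its family, 10.4-fold. KRT10 fell 18.1-fold to 37.6 ± 22.3 CPM (log2 −4.18, SE 0.447, adjusted p = 1.11e-07), the envelope protein FLG 5.48-fold, the desmosomal cadherins DSG1 and DSC1 4.69-fold and 4.41-fold, and the receptor kinase EPHA4 had a log2 difference of −3.41. As a list, the early differentiation markers had no camera call (adjusted p = 0.0733). In total 2160 genes rose and 1969 fell. Of 18 antimicrobial genes 16 rose (17 adjusted over the list alone; camera 1.05e-37, adjusted p = 3.95e-05 with an estimated correlation), of 17 IL-17 target chemokines and regulators 14 rose, also adjusted over the list alone (3e-22 and 0.000633), and of 26 cell-cycle genes 15 fell (21 adjusted over the list alone; camera 6.16e-06, adjusted p = 0.491 with an estimated correlation). The total of 4129 moved to 2640 and 2631 without batch 3 or 5.

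Whether the cytokines together did more than the product of their separate effects was tested as an interaction, and edgeR called 0 genes, with 171 at an unadjusted p under 0.05 and 0 called by DESeq2. IL23A had log2 values of 0.19, 3.11 and 4.96 for IL-17A, TNF and both, a departure of 1.66 (SE 0.639, adjusted p = 1). The departures were 1.22 for DEFB4A (SE 1.27), 1.54 for CSF3 (SE 1.35), 1.22 for IL8 (SE 0.93) and 0.19 for LCN2 (SE 0.381), each with adjusted p = 1. The list of late cornified-envelope markers departed downward (camera 4.07e-06, adjusted p = 0.149 with an estimated correlation). Without batch 4, 1 gene was called.

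The responses with Tet show what the cytokines did in cells with the knockdown. IL-17A gave LCN2 0.96 (SE 0.268, adjusted p = 0.624, edgeR), NFKBIZ 0.71 (SE 0.197, 0.611) and ZC3H12A 0.64 (SE 0.139, 0.0787), none past the threshold. These 3 were picked from the genes called without Tet, a choice that favours smaller values here. SAA4, with a larger response without Tet than these 3 (log2 2.47), passed in both arms. The values of SPRR2E (1.62 against 1.43 without Tet), SPRR2A (1.61 against 1.30) and the protease inhibitor PI3 (1.09 against 1.05) were not smaller. SPRR2E and SPRR2A were among the leading genes of the response with Tet, a choice that favours larger values there. SAA4 rose 3.74-fold (log2 1.90, SE 0.296, adjusted p = 0.00397) and SPRR2E 3.08-fold (log2 1.62, SE 0.246, adjusted p = 0.00397). Their calls ended without the Tet control of batch 3 (adjusted p = 0.0764 for SAA4 and 0.0699 for SPRR2E), and that of SPRR2E also without the Tet IL-17A library of batch 2 (adjusted p = 0.05). In total 15 genes rose and 0 fell, 416 had an unadjusted p under 0.05, and DESeq2 called 21. Of 18 antimicrobial genes 4 rose (11 adjusted over the list alone; adjusted p = 1.41e-05 with an estimated correlation), of 15 small proline-rich and LCE3 genes 7 rose (11 adjusted over the list alone; 0.000199), and of 17 IL-17 target chemokines and regulators 0 passed over all genes and 5 rose adjusted over the list alone (0.0191). Desquamation proteases ran upward by camera (6.32e-10, adjusted p = 0.117 with an estimated correlation). The count of 15 was 0, 2, 3 and 3 without batch 2, 3, 4 or 5. It was 7, 0 and 4 without the Tet control of batch 2, 3 or 5, and 1 and 3 without the Tet IL-17A library of batch 2 or 4.

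TNF with Tet raised CSF2 23.3-fold (adjusted p = 5.57e-06), the decoy receptor IL1R2 15.8-fold and ICAM1 9.94-fold, and lowered the proteoglycan SPOCK1 10.8-fold and KRT1 5.13-fold (adjusted p = 0.0034). In total 1597 genes rose and 1538 fell by edgeR, and 23 of 27 TNF and NF-kB targets rose (26 adjusted over the list alone; adjusted p = 0.00068 with an estimated correlation). Both cytokines with Tet raised DEFB4A 112-fold (SE 0.505 on the log2 scale, adjusted p = 1.35e-09), CSF2 30.6-fold, IL1R2 23.8-fold, CSF3 14.3-fold, C15orf48 14.1-fold, LCN2 7.67-fold, SAA4 7.54-fold and NFKBIZ 2.68-fold, and lowered KRT1 13.8-fold, the growth factor-like gene IGFL2 12.2-fold, SPOCK1 11.6-fold and KRT10 3.15-fold (adjusted p = 0.00363). In total 1994 genes rose and 1946 fell, and of 18 antimicrobial genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.000673 with an estimated correlation). The total of 3940 was 2550 without batch 2. Of the genes that TNF raised without Tet, 1650 of 1667 also had a positive difference with Tet, and 1117 passed in both arms, against 187 expected by chance. For both cytokines 2080 of 2160 were positive and 1326 passed in both arms, against 303. For IL-17A alone 20 of 20 were positive with Tet and 9 passed in both arms, against 0.0211 expected.

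**Figure D4:**
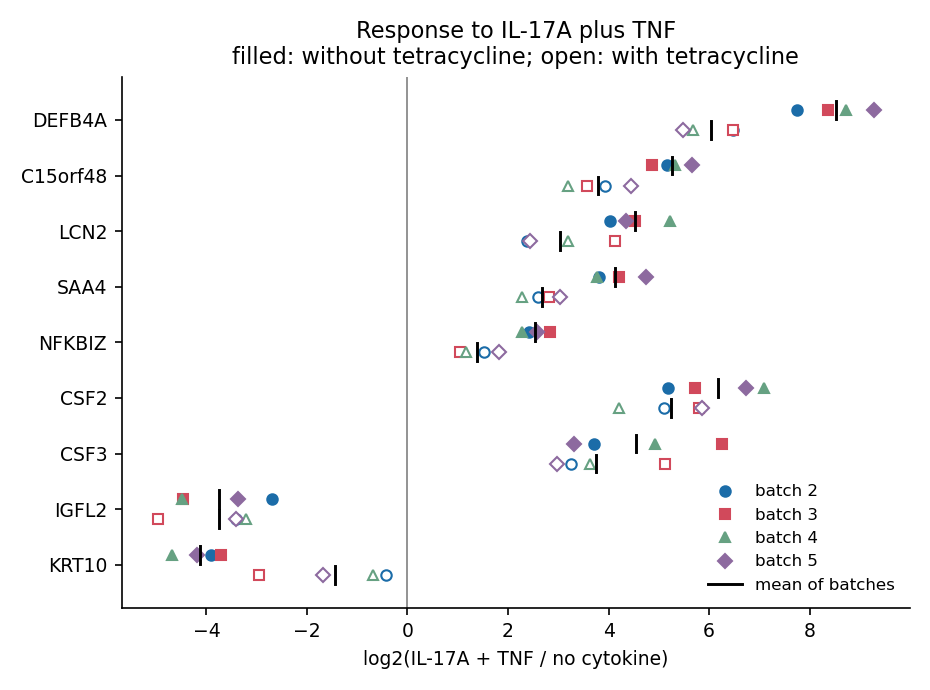
Log2 difference between cells with IL-17A plus TNF and cells without cytokine, in each of 4 batches, for selected genes. Filled points are without Tet and open points with Tet; LCN2 lies between 4.03 and 5.23 without Tet.

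The difference between the responses with and without Tet was tested as an interaction, which asks whether the response changes with Tet. It cannot part loss of TRAF3IP2 from the drug itself, since no group had Tet without the hairpin. ST5, a regulator of small GTPases, was the only gene edgeR called, for both cytokines together (log2 −1.18, SE 0.179, adjusted p = 0.00916), where 1001 genes had an unadjusted p under 0.05 and DESeq2 called 28. ST5 went from 40.5 ± 10.4 to 72.6 ± 30.4 CPM without Tet and from 37.4 ± 9.98 to 28.7 ± 8.56 CPM with Tet (SD, n = 4). The difference was negative in all 4 batches (−0.698, −1.62, −0.677 and −1.74), but the call ended without batch 2, 3 or 5 (adjusted p = 0.119, 0.247 and 0.412). LCN2 had −1.55 (SE 0.38, adjusted p = 0.213), NFKBIZ −1.12 (SE 0.278, 0.213), ZC3H12A −0.99 (SE 0.196, 0.104) and KRT10 2.52 (SE 0.575, 0.166). The responses of these genes were thus smaller with Tet, by values that did not pass. Without cytokine, LCN2 had already risen with Tet from 20 to 78.6 CPM and KRT10 had fallen from 707 to 113 CPM. A smaller response of LCN2 is therefore not a lower level: averaged over the 4 conditions, LCN2 was 2.02-fold higher with Tet. For IL-17A alone edgeR called 0 genes (159 at an unadjusted p under 0.05; DESeq2 0), with LCN2 at −1.07 (SE 0.38), NFKBIZ at −0.85 (SE 0.278) and ZC3H12A at −0.67 (SE 0.196), each with adjusted p = 1. For TNF alone edgeR also called 0 (311 at an unadjusted p under 0.05; DESeq2 0), with LCN2 at −0.76 (SE 0.381, adjusted p = 0.999). For both cytokines 4 of 18 antimicrobial genes had a smaller response adjusted over the list alone (camera 2.26e-08, adjusted p = 0.108 with an estimated correlation), and so did 4 of 17 IL-17 target chemokines and regulators (0.000579, adjusted p = 0.576 with an estimated correlation). The count of 1 for both cytokines was 0 without batch 2 or 5, 3 without the library with both cytokines and no Tet of batch 2, 2 and 3 without the untreated control of batch 3 or 4, 8 without the Tet control of batch 3, and 9 without the library with Tet and both cytokines of batch 5.

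A block for each batch within each Tet arm, chosen after the data were seen, gave 26 called genes for both cytokines, 5 with a positive and 21 with a negative interaction. ZC3H12A had 1.80 without and 0.82 with Tet (interaction −0.996, adjusted p = 0.0237), NFKBIZ 2.55 and 1.42 (−1.11, 0.0323), and KRT10 −4.18 and −1.66 (2.69, 0.0206). NOS2, the nitric oxide synthase of inflammation, had 6.26 and 0.88 (−5.41, 0.0256) and VNN3, a pantetheinase, 4.41 and 2.95 (−1.50, 0.0214). These genes were chosen after their values were seen. With no replicate block, 0 genes were called for this interaction. Genes chosen by their response in 1 pair of batches were also measured in the other pair. The 3 genes rising with IL-17A in batches 2 and 3 had medians of 2.30 without and 0.958 with Tet in batches 4 and 5 (difference −1.02, −1.34 and −0.697 by batch, smaller in 3 of 3), and only 1 gene could be chosen in batches 4 and 5. The 1742 genes rising with both cytokines in batches 2 and 3 had medians of 0.588 without Tet and 0.507 with Tet in batches 4 and 5. The 1446 genes chosen in batches 4 and 5 had 0.629 and 0.527 in batches 2 and 3. The median difference was −0.0867 (−0.0218 and −0.132 by batch) and −0.089 (0.00713 and −0.228 by batch). TNF alone gave similar values. Both sets had TNF and were measured against the same control libraries, so these medians cannot show whether a decrease was particular to IL-17A. The 1465 genes rising with TNF in batches 2 and 3 had −0.0553 (0.051 and −0.154 by batch). The 877 chosen in batches 4 and 5 had −0.0809 (−0.0854 and −0.0796 by batch). For both cytokines, genes chosen in batches 2 and 3 at a 2-fold change or more had −0.218 (−0.294 and −0.11 by batch). Those chosen in batches 4 and 5 had −0.168 (0.0312 and −0.403 by batch).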

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

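The tests weighed here were chosen only after the results were seen, except those of the guide's usual matching segment and of the stress-response list, written before.

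Single libraries stood apart from the other 3 of their group in 4 of 32 measures, and single batches did so in 8 of 204 sets of gene differences, where chance gives about 1 in 20 (Dixon's ratio above its 95% critical value). With IL-17A and no Tet, batch 3 had 15739 symbols with a count against 16211 to 16255. With TNF and no Tet, the 20 most abundant genes took 14.2% of counts in batch 2 against 16.1% to 16.3%, and TRAF3IP2 was at 78.2 CPM in batch 5 against 89.8 to 91.8. With Tet and both cytokines, batch 2 had 29.6 M counts against 35.1 to 36.0.

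Among genes, MMP13 differed by −0.964 with Tet in batch 4 against −3.02 to −2.84 in the other batches. IL1F9 rose by 0.868 with IL-17A in batch 2 against 1.31 to 1.37. With TNF, SOX6 differed by −2.97 in batch 4 against −1.70 to −1.44, and LCN2 by 3.48 against 1.85 to 2.03. With both cytokines, DSC1 differed by −4.50 in batch 4 without Tet against −1.56 to −1.38, and IGFL2 by −4.97 in batch 3 with Tet against −3.42 to −3.21. The interaction of Tet and both cytokines was −2.12 for C15orf48 in batch 4 against −1.30 to −1.21. The departure from the product of the separate cytokine effects was −1.52 for LCN2 in batch 4 against 0.583 to 0.851. Batch 4 held 6 of these 8, and no explanation for that was tested. ST5 differed between the arms, with an interaction of −1.18 that edgeR called.

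Many genes other than TRAF3IP2 fell with Tet. Matches to the guide's usual segment do not account for it: the heptamer opposite guide positions 2 to 8 ranked at percentile 33 among all heptamers by the median change of genes that carry it. The values met the bound set beforehand against tetracycline acting through the integrated stress response, but they do not settle it. The list's median was −0.159 and 1 of its 20 members rose. That median leans on batch 4, since the mean of the batch medians was 0.337 without it, a check added after the data were seen. The 0.337 in turn leans on batch 3, whose libraries without Tet were low in these genes (ASNS 119 CPM against 361 to 482). The stress response is therefore not excluded. A guide shifted by 2 bases may contribute, because the heptamer opposite positions 4 to 10 ranked at percentile 0.0923, but it was the lowest of 15 windows of the guide, so its percentiles in the batches (0.123, 0.08, 0.954 and 0.431) restate that choice; with the hairpin off it ranked at 11.9 for TNF and 4.81 for both cytokines, the median change of genes with 2 or more sites (−0.025) was not below that of genes with 1 (−0.0414), and 84.7% of the falling genes in the summed counts carried no site, which excludes it as the direct cause for all of them. Genes with a site followed by A had a lower median than genes with 1 site, at −0.101. Loss of Act1 and the drug itself cannot be told apart, since no group had Tet without the hairpin.

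ATF4 and integrated stress response targets were low with Tet in batch 4. Knockdown of TRAF3IP2 itself as the cause is argued against by the other batches, where the list's median was 0.0711, 0.708 and 0.233 although TRAF3IP2 fell by 2.77 on the log2 scale or more; the 0.708 of batch 3 goes with low levels without Tet there (ASNS 119 CPM against 361 to 482), so it shows no rise beyond the other batches' levels. The explanation by 1 aberrant library is argued against by the list's being low in all 4 conditions of batch 4. A difference between cultures of batch 4, such as its medium, could not be tested.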

How the results depend on the processing

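The summed counts and the block within each Tet arm were chosen only after the data were seen; the other alternatives were set beforehand. Median-of-ratios scaling, no low-count filter and the stricter filter left each of the 12 counts of called genes within 1.5 times, and no called value of a named gene changed sign under any alternative. Values below the threshold did: TRAF3IP2 in 5 cytokine responses or interactions, and the departure of LCN2 from the product of the separate cytokine effects. That departure was 0.19 and turned negative with no replicate block, in batches 4 and 5 alone and without batch 3. In each case below the cause was not tested, unless fewer libraries or a stricter rule is itself the change.

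Requiring a 2-fold change left 309 genes for Tet without cytokine, 444 for the mean Tet effect, 629 and 868 for TNF and both cytokines without Tet, and 609 and 895 with Tet. With no replicate block the counts were 21 and 3061 for Tet without cytokine and on average, 1, 487 and 862 for IL-17A, TNF and both without Tet, 0, 429 and 866 with Tet, and 0 for the interaction of Tet and both cytokines. DESeq2 called 28 genes for that interaction. Fits on the compared libraries alone called 267 for Tet without cytokine, 73 and 23 for IL-17A without and with Tet, and 0 for the interaction with both cytokines.

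Batches 2 and 3 alone gave 71 and 4257 for Tet without cytokine and on average, 2, 1436 and 2000 for IL-17A, TNF and both without Tet, 0, 866 and 1799 with Tet, and 0 for the interaction with both. Batches 4 and 5 alone gave 564 for Tet without cytokine, 3, 583 and 1114 without Tet, 0, 899 and 1258 with Tet, and 0 for the interaction with both. The block within each Tet arm gave 4953 for TNF without Tet and 26 for the interaction with both. The summed counts gave 1191 for the mean Tet effect.

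Leaving out 1 library or batch at a time gave 201 to 2346 genes for Tet without cytokine, 5558 to 7932 for the mean Tet effect, 3 to 22, 1818 to 3054 and 2631 to 4115 for IL-17A, TNF and both without Tet, and 0 to 15, 2093 to 2915 and 2550 to 3670 with Tet. It gave 0 to 0 for the interactions with IL-17A and with TNF, 0 to 9 with both, and 0 to 1 for departure from the product of the separate effects.

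The held-out difference for TNF genes chosen in batches 4 and 5 was −0.0736 under the stricter filter and −0.14 when chosen at a 2-fold change, against −0.0809 in the main setting. It was −0.216 for TNF and −0.218 for both cytokines when chosen at 2-fold in batches 2 and 3, and −0.168 for both when chosen so in batches 4 and 5. Of the 86 list calls by camera, 23 held with an estimated correlation; without the block camera called 86, of which 79 were shared. Over the same 228 pairs fry called 54, not all of them among camera's. Among 204 named values, 48 lost their call without the block, 44 in batches 2 and 3 alone, 36 in batches 4 and 5 alone and 9 in the compared libraries alone, where 4 gained one. In the summed counts IL17RA and IL17RC were among those that lost theirs. Low counts limit DEFB4A without cytokine, at 6 counts over 4 libraries.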

Other observations

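The tests by splits of the libraries and those of the site opposite guide positions 4 to 10 were chosen only after the results were seen.

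Other splits of the 8 libraries of a two-group comparison were counted by edgeR on those libraries alone, in 32 splits that could be fitted. In each, only the real split was as large: for Tet without cytokine (267 genes; highest other 135), for IL-17A, TNF and both cytokines without Tet (73, 4285 and 3502; highest other 6, 0 and 0) and with Tet (23, 3221 and 3357; highest other 16, 0 and 0). A share of 1 in 32 excludes chance only where libraries can be exchanged between batches. Each library correlated best with a library of its own batch, so this share does not exclude chance here. The 8 splits that part all pairs from a batch are too few for a share under 0.05, and their highest other was 0 in each of these comparisons. For the mean Tet effect 1 of 41 splits was as large (7443 genes, highest other 0). Those splits also exchanged libraries between batches, so that share does not exclude chance either. When whole Tet arms were exchanged within batches, the 8 splits were too few for a share under 0.05, and the highest other split called 6214 genes, so the arms of each batch form a structure of the samples. With summed arms the 8 splits were also too few (1191 genes; highest other 0). For the 3 interactions of Tet and cytokine and for the departure from the product of the separate effects, the real split called 0 genes in a fit of the compared libraries. By construction 61 of 61 splits then called as many, and nothing was tested. The highest splits called 18, 266, 521 and 27 genes, which points to a structure of the samples.

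Of the 20 genes falling most clearly with Tet, 9 carried a match to the heptamer opposite guide positions 4 to 10, and 7.46% were expected. GBAS, NHP2L1, SEPT10 and CBR4, which carry it and were chosen after their values were seen, had log2 differences of −1.51, −0.67, −0.92 and −1.03. In the summed counts 11.3% of genes with a site and 4.92% of genes without fell. A guide that starts 2 bases later than designed may explain part of this, at percentile 0.0923 among heptamers, though that segment was picked as the lowest of 15. Where the hairpin was not turned on, the percentile was 11.9 for TNF and 4.81 for both cytokines. With Tet, the 86 genes with 2 or more sites were not lower than those with 1. The 325 genes with a site followed by A were lower (median −0.101 against −0.0414 with 1 site), and 15.1% of them fell in the summed counts. Of the 20 genes rising most clearly with Tet, 1 carried a site, and 6.12% were expected.

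The Tet effect differed between batches in 6847 genes (48.2%) when the 4 conditions of an arm were taken as independent replicates, which they are not. Its root mean square over genes was 0.397, 0.304, 0.54 and 0.364 in batches 2 to 5, and correlations across genes between pairs of batches ran from 0.132 to 0.668, where genes are not independent replicates.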
